A study of Mus musculus with 2 samples.

How the data were processed

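Poly(A)-selected RNA from mouse olfactory bulb was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. For each library a gene table (69691 rows) and a transcript table (129984 rows) were used, together with a text listing of the library's files. Per the deposited listing, the tables derive from a transcriptome alignment on assembly mm10 (GRCm38) with GENCODE annotation M4. The aligner, the quantifier, their versions, the library kit and the strand setting of the counting are not given in the sources used here. The signal tracks listed are not split by strand. Reads from overlapping, antisense or near-identical genes can therefore be shared, and such genes are uncertain.

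The expected counts deposited by the authors are estimated reads per gene or transcript, not normalized, and need not be whole. The deposited TPM values are scaled over all rows of a table, so the phiX174, tRNA and mitochondrial rows lower the TPM of every other gene. The files also hold, per the file headers, a posterior mean TPM, a posterior mean count and, as score values on the TPM scale, lower and upper credibility bounds whose level the files do not state. The posterior mean gives every row a value above 0 even where its count is 0. The deposited percent of a gene's expression from each transcript was not read directly, and the shares were recomputed from transcript TPM.

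Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same assembly, by identifier without version. Of 43346 gene rows 42462 were matched and 884 were not. The tRNA rows (26248), ERCC rows (96) and the phiX174 row were kept out of gene counts and library sizes. A total of 27 gene lists with 269 distinct genes, of which 268 were matched, was fixed before the data were examined, as were the tests, most other settings and the rule for named genes. For levels, that rule took the 20 nuclear protein-coding genes with the highest mean TPM, the 4 highest detected members of each list and up to 3 members below the minimum. All members of the receptor subunit, neuropeptide and Y-linked lists could be named. For the replicate comparison, it took the 10 genes with the largest scaled ratio each way with a mean TPM of at least 5 and non-overlapping intervals, and the 3 members furthest from 0 of any list outside the percentiles. For isoforms, it took listed genes with a mean TPM of at least 10 and a second transcript of at least 30% in both libraries, and up to 5 genes whose main transcript differed. Genes outside the rule, among them Rag1, Satb1 and the other T-lineage genes, the mitochondrial and non-coding RNAs and lower-ranked list members printed with their counts, were chosen after their values were seen.

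A gene was detected at a mean TPM of at least 1 over the 2 libraries. List levels are given as summed expected counts with exact Poisson 95% intervals and as mean and SD of the summed TPM (n = 2). Shares of counts have Wilson 95% intervals, ratios of 2 counts have exact binomial (Clopper-Pearson) 95% intervals, and a count of 0 allows up to 3 counts. Count ratios between the libraries were divided by the ratio of their annotated gene counts, not by the TMM factors. A bound against a count of 0 uses 3 counts there and takes the other count as measured. These cover counting error only. Annotated genes had 17165 counts in replicate 1 and 17481 in replicate 2, and 92 and 130 genes had at least 10 counts, so most single genes rest on a few reads. Libraries were scaled with TMM factors from edgeR 4.0.16 (0.960 and 1.04) in R 4.3.3 on expected counts rounded to whole numbers, and the common dispersion was estimated with an intercept-only design. No test between groups was possible with 1 group. A gene differed between the libraries at a scaled TPM ratio of at least 2 with credibility bounds that did not overlap after scaling. The median log2 ratio of each list, with a pseudocount of 0.5 TPM, was placed among 10000 random lists matched on mean TPM in 20 bins. Correlations across genes used log2(TPM + 1). Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

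The steps were tested on simulated counts drawn from the real means, with intervals drawn from the counts and the scale of the libraries known. Among genes with at least 10 counts, the rule for genes that differed recovered 4% of 50 genes changed 2-fold, 54% of 50 changed 4-fold, 66% of 50 changed 8-fold and 64% of 50 changed 16-fold, in a simulation of 8882 genes. It called 2 of 8682 unchanged genes. The list shift called 4 of 77 unchanged lists and 37 of 87 lists changed 4-fold. The counts simulated for both rules held counting noise only. The real libraries varied by more than that, so these rates need not hold for the real calls. Simulated coefficients of variation of 0.1, 0.4 and 1 were estimated as 0.0604, 0.383 and 0.937 over 8932 genes.

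The other settings chosen then were each replicate left out, the posterior mean TPM, other minimum levels, pseudocounts and folds, protein-coding genes only, TPM rescaled over nuclear protein-coding genes, no rescaling, and size factors and dispersions from DESeq2 1.42.0. Because a TPM minimum of 1 took in nearly every gene with a read, minimums of 3 or 10 expected counts over both libraries and a comparison of summed list counts were added after seeing the data. Panels of T-lineage, neuronal, blood and other organs' genes were also added then.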

Results

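Polyadenylated RNA longer than 200 bases was sequenced from the olfactory bulb of adult male mice, labelled as strain B6NCrl and aged 8 weeks. The olfactory bulb is the part of the forebrain that receives the axons of the nose's sensory neurons. The series holds 2 libraries in 1 group, labelled as biological replicates 1 and 2. Both carry the same donor record, and the label names an individual animal for replicate 1 only, so the spread between them may be partly technical. No condition was contrasted, and the comparisons are therefore the level of each cell class's genes, the use of isoforms, and the difference between the 2 libraries. With 2 replicates an exact sign-flip test cannot give a p below 0.5, so none is given.

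The gene tables held few counts. How many reads were sequenced, and whether the tables count all of them, is not given in the sources used here, so every count, floor and zero below describes these tables. Expected counts summed to 39683 in replicate 1 and 35487 in replicate 2. The row for phiX174, a bacteriophage whose DNA is commonly added to sequencing runs as a control, took 22472 counts (56.6%, Wilson 95% interval 56.1% to 57.1%) in replicate 1 and 17985 (50.7%, 50.2% to 51.2%) in replicate 2. Annotated mouse genes kept 17165 and 17481 counts. Nuclear protein-coding genes held 65.0% and 72.8% of those gene counts. A gene at 0 in a library could hold up to 3 counts there, which is 0.0175% of the gene counts in replicate 1 and 0.0172% in replicate 2. The labels name a set of spike-in controls, and all 96 rows for ERCC spike-ins stood at 0 in both libraries, which allows up to 0.00756% and 0.00845% of all counts. Intervals and floors here cover counting error only.

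**Figure D1:**
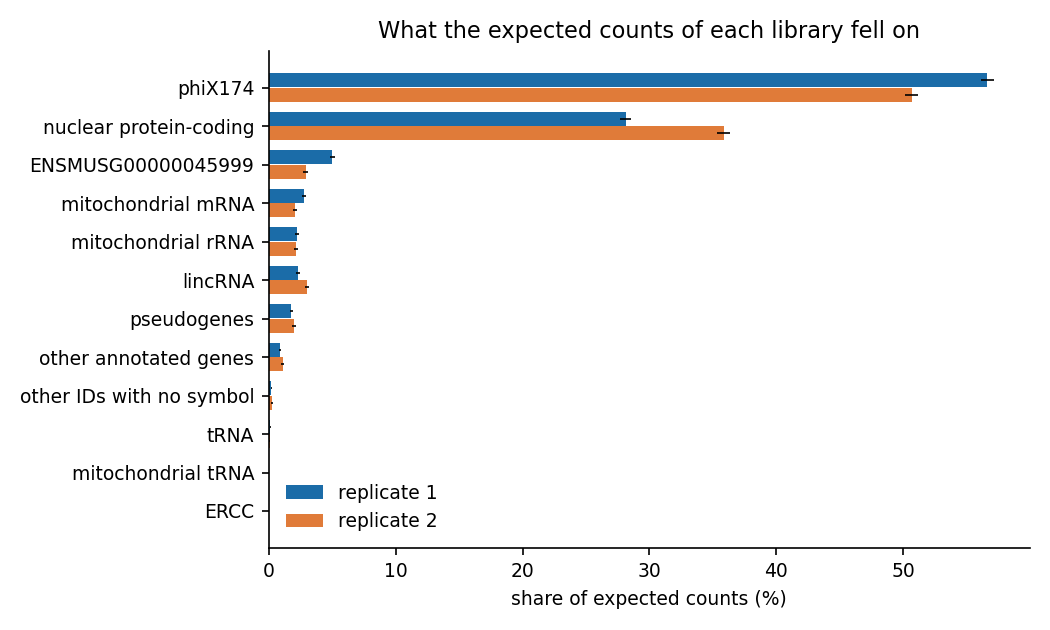
Share of all expected counts (percent) by kind of row, for replicate 1 (blue) and replicate 2 (orange), with Wilson 95% intervals as error bars. The phiX174 row held 56.6% and 50.7% of the counts, more than any other kind of row, and ERCC rows held none.

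Reads on mouse genes fell first on a few abundant RNAs. The gene ENSMUSG00000045999, to which no symbol was matched, held 1983 counts in replicate 1 (11.6% of gene counts) and 1027 in replicate 2 (5.87%). The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 634 and 334 counts and 254 and 421 counts, and the 13 mitochondrially encoded protein genes summed to 6.40% and 4.13% of gene counts. Among non-coding RNAs, Gm42418 had 291 and 620 counts, Malat1, a nuclear RNA, had 162 and 286, and Meg3, an imprinted RNA of neurons, had 56 and 52.4. Nuclear protein-coding genes were led by Lars2, a mitochondrial leucyl-tRNA synthetase, with 188 and 257 counts. Its counts, like those of Gm42418 and some other genes here, were not whole numbers. Part of those reads was shared with other rows, so such levels are uncertain. Eef1a1, a translation elongation factor, had 40.6 and 56.1 counts (2487 ± 488 TPM, SD, n = 2). Actb, the cytoplasmic actin, had 40.9 and 18.2 counts, and Snap25, a protein of synaptic vesicle fusion, had 19 and 15 (613 ± 3.80 TPM). The other nuclear genes among the 20 highest by mean TPM included the apolipoproteins Apoe (8 and 7 counts) and Apod (3 and 6), the sodium pump subunit Atp1b1 (18 and 22), the chaperones Hspa8 (10.2 and 10.9) and Hsp90ab1 (6 and 20), the actin-binding peptide gene Tmsb4x (6 and 30) and the selenium carrier Selenop (16 and 11). The 83 ribosomal protein genes together held 0.930% and 0.980% of gene counts, with 63 of them counted.

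A mean TPM of at least 1 counted 8932 genes as detected. At this depth 1 read on a transcript of 2000 bases is worth 27.7 TPM in replicate 1 and 28.7 TPM in replicate 2, so the minimum took in nearly every gene with any read (8940 genes, of which 3348 had counts in both libraries). A minimum of 10 counts over both libraries, chosen after seeing the data, left 392 genes, 359 of them protein-coding.

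Genes of GABAergic interneurons and of astrocytes, the most abundant neuron class of the bulb and its main support glia, held the most counts of the cell class lists. The 17 GABAergic genes, of which 16 were detected, summed to 47 counts in replicate 1 and 61.6 in replicate 2 (1486 ± 780 TPM, SD, n = 2; 934 in replicate 1 and 2037 in replicate 2). Its 4 highest members by mean TPM were Meis2, a transcription factor of these cells (5 and 11 counts), Gad1, which makes GABA (11 and 13), the calmodulin-binding protein gene Pcp4 (1 and 3.86) and Dlx1, a transcription factor (2 and 5.73). Of the 12 astrocyte genes 11 were detected, with 50 and 69 counts (1465 ± 497 TPM). These were led by the glutamate transporters Slc1a2 (24 and 29 counts, 550 ± 185 TPM) and Slc1a3 (8 and 13, 179 ± 3.51 TPM), the bicarbonate transporter Slc4a4 (7 and 8) and the glycolytic enzyme gene Aldoc (3 and 8). The 12 genes of myelinating oligodendrocytes had 6 detected members and 14 and 26 counts (719 ± 32.6 TPM), from the myelin genes Mbp (5 and 6), Plp1 (7 and 10), Cnp (1 and 1) and Mobp (0 and 7). Olfactory ensheathing glia, which wrap the sensory axons, had 5 of 8 genes detected with 6 and 13 counts (936 ± 631 TPM), led by Apod and by Fabp7 (0 and 4 counts). Ngfr, Prss56 and Sox10 of that list stood at 0 in both libraries.

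The genes of mitral and tufted cells, the projection neurons of the bulb, held fewer counts. Of 9 genes 4 were detected, with 16 and 9 counts (201 ± 127 TPM): Reln, a secreted guidance protein (4 and 6), Cdhr1, a cadherin (10 and 1), Slc17a7, a vesicular glutamate transporter (1 and 2), and Eomes (1 and 0). The remaining 5, among them Tbx21, Tbr1 and Slc17a6, stood at 0. Dopaminergic and calcium-binding periglomerular genes had 3 and 4 counts over 5 detected of 10, with Th, the enzyme that limits dopamine synthesis, at 0 and 1 and Calb2 at 1 and 2. Migrating neuroblast genes had 11 and 13.1 counts over 6 of 9, including Dcx, a microtubule protein of young neurons (6 and 3), Robo2 (3 and 3) and Sox11 (0 and 3). Cell division genes had 10 and 29 counts over 8 of 12, with Mki67 at 5 and 14 and Top2a at 1 and 7.

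The other cell class lists ranged from 0 to 23 counts over both libraries. Microglial genes had 5 and 2 counts (6 of 12 detected), endothelial genes 4 and 5 (6 of 10), mural cell genes 4 and 2.06 (3 of 8) and choroid plexus genes 1 and 2 (3 of 10). Meningeal fibroblast genes had 11 and 7 counts, of which Ptgds, a prostaglandin synthase, made 8 and 6. Oligodendrocyte precursor genes had 0 and 1 count, on Olig1. Olfactory sensory neuron genes had 1 and 3 counts over 4 of 12, with Omp, a marker of mature sensory neurons, at 0. Genes of cortical projection neurons had 7 and 16 counts over 6 of 10, among them Cux2 (0 and 9), Bcl11b (3 and 4) and Foxg1 (0 and 3). The remaining members, among them Satb2, Fezf2 and Neurod6, stood at 0 in both libraries. Blood cell genes (7), striatal projection neuron genes (8) and the 6 matched genes of olfactory epithelium support cells and glands had 0 counts in both libraries. A seventh gene of that list, Ugt2a1, was not matched to a row.

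**Figure D2:**
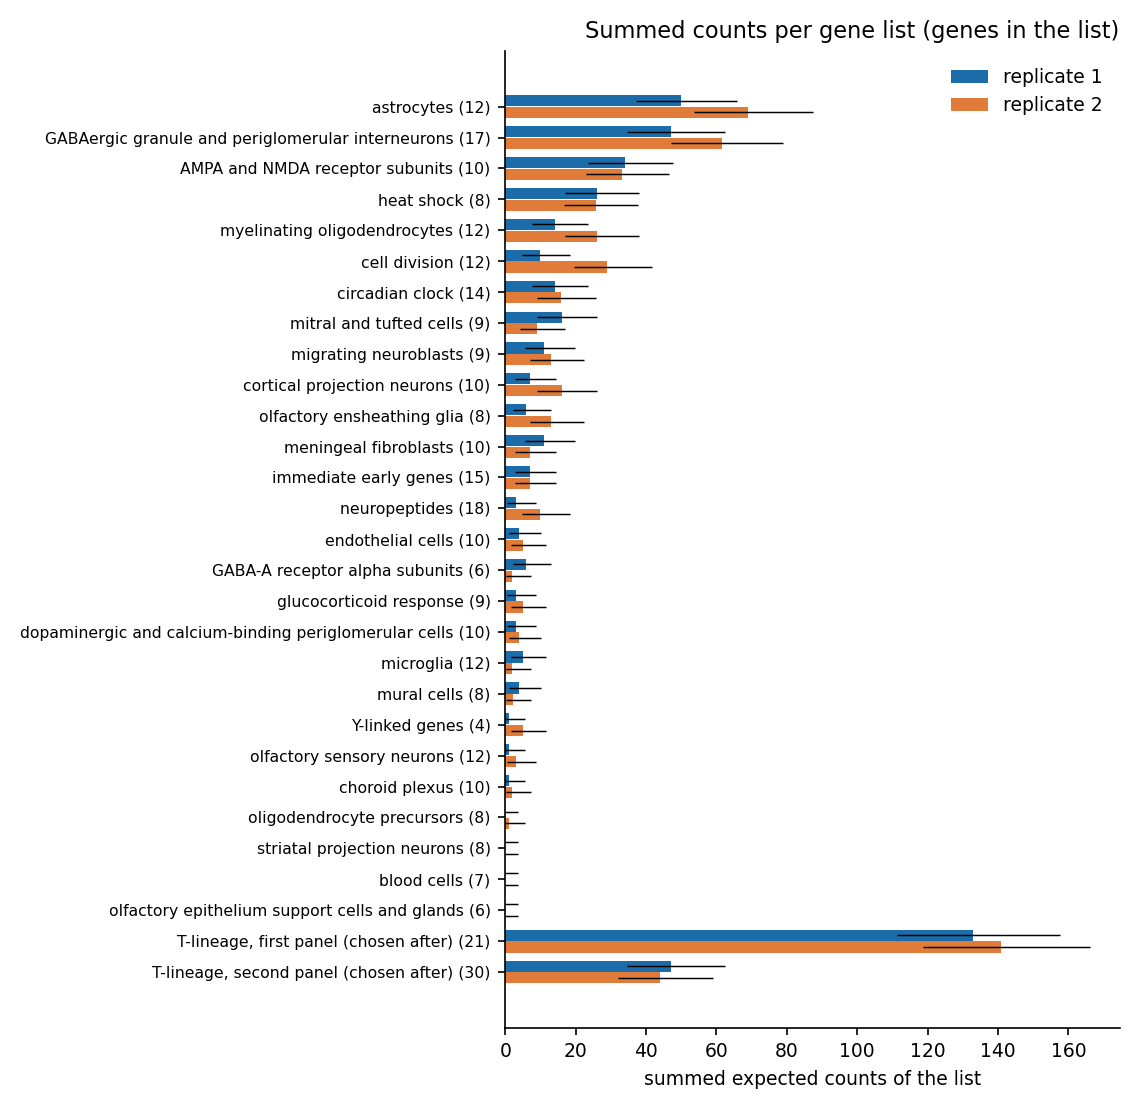
Summed expected counts of each gene list (horizontal axis, counts) in replicate 1 (blue) and replicate 2 (orange), with Poisson 95% intervals as error bars and the number of genes in brackets. Astrocyte genes (50 and 69 counts) and GABAergic genes (47 and 61.6) lead the lists fixed in advance, and the 2 T-lineage panels at the bottom were chosen after values were seen.

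Genes of the T-cell lineage were also counted in both libraries. Rag1, which cuts DNA to assemble antigen receptor genes (chromosome 2, 101638282 to 101649501, GRCm38), had 25 and 21 counts and ranked among the 25 genes with the most counts. Satb1, a chromatin organizer of thymocytes that neurons also express, had 16 and 24. A panel of 21 T-lineage genes, put together after these values were seen, had 133 and 141 counts with 20 members counted, including Tcf7 (13 and 9), Ptprc (14 and 12), Cd4 (8 and 8), Themis (7 and 8), Lck (8 and 5) and Dntt (9 and 6). A further panel of 30 T-lineage genes whose values had not been looked at had 47 and 44 counts with 23 members counted. Together both panels held 1.05% and 1.06% of gene counts. A panel of 20 neuronal genes, also chosen afterwards, had 107 and 125 counts with 19 members counted.

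Genes of GABA synthesis outweighed those of vesicular glutamate transport in both libraries. Gad1 and Gad2 summed to 15 and 19 counts, against 1 and 2 counts for Slc17a6 and Slc17a7. The ratio of their summed TPM was 13.9 in replicate 1 and 8.04 in replicate 2 (10.98 ± 4.16, SD, n = 2). The count ratio was 15.0 (exact binomial 95% interval 2.31 to 631) and 9.50 (2.29 to 84.1). Both intervals exclude 1, and their width comes from the 1 and 2 counts below the line. The ratio sets synthesis against vesicular transport, which are unlike steps. Slc32a1, the vesicular GABA transporter gene, had only 1 and 0 counts, so the ratio holds for the markers used here.

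All 10 subunit genes of AMPA and NMDA glutamate receptors were detected, with 34.0 and 33.1 counts (481 ± 28.8 TPM). Grin2b had 12 and 10 counts, Gria2 7.03 and 10, Gria1 3 and 4, Grin1 5 and 2.1 and Gria3 3 and 3, and the other 5 had 2 or fewer in each library. Of the 6 GABA-A alpha subunit genes, Gabra4 (3 and 0), Gabra3 (2 and 1) and Gabra1 (1 and 1) were detected, and Gabra2, Gabra5 and Gabra6 stood at 0. Of 18 neuropeptide genes 5 were detected, with 3 and 10 counts: Scg2 (1 and 6), Penk (0 and 3), Npy (1 and 0), Nts (0 and 1) and Adcyap1 (1 and 0). The Y-linked Eif2s3y (1 and 3 counts) and Ddx3y (0 and 2) were counted, and Kdm5d and Uty stood at 0.

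Among genes that respond to activity, time of day, glucocorticoids or heat, the heat shock list held the most counts. Immediate early genes had 7 counts in each library over 8 of 15 genes, with Btg2 at 3 and 3, Egr1 at 2 and 0 and Fos at 1 and 0. Circadian clock genes had 14 and 15.9 counts over 9 of 14, led by Bhlhe41 (2 and 3), Tef (7 and 2) and Dbp (0 and 3). Glucocorticoid response genes had 3 and 5 counts over 4 of 9, with Fkbp5 at 1 and 4. Heat shock genes had 26.0 and 25.7 counts over 5 of 8, mostly from the chaperones Hspa8 and Hsp90aa1 (11.9 and 8.87 counts). Hsph1 had 2 and 4 counts, Dnajb1 had 0 and 1, and Hspa1a and Hspa1b stood at 0.

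No chemoreceptor gene was counted. The 1477 genes of the odorant (1166 Olfr), trace amine (16 Taar) and vomeronasal receptor families (174 Vmn1r and 121 Vmn2r) had 0 counts in both libraries. Their sum could therefore reach 0.0175% of gene counts in replicate 1 and 0.0172% in replicate 2 without being seen.

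Isoform shares rested on few reads in most genes. Over the 6154 detected genes with at least 2 annotated transcripts, the median share of the main transcript was 100% in both libraries, which a gene with 1 read takes by construction. Among 313 such genes with at least 10 counts, the median was 68.6% and 64.2%. Of the listed genes, Plp1, the main myelin membrane protein, had a second transcript of at least 30% in both libraries. Its transcript ENSMUST00000113085.1 held 60.8% and 66.5% and ENSMUST00000033800.8 held 39.2% and 33.5%, on 7 and 10 counts. The main transcript differed between the libraries in 1757 of 2543 genes counted in both (69.1%), and in 218 of 311 with at least 10 counts. Those 10 counts are a total over both libraries, so 1 library can hold few of them. How often counting noise or shared reads alone would change the main transcript was not tested. These numbers therefore do not show that isoform use differed. The changes of largest share, in Atp5f1, Hdac7, Vps13d, Rasa1 and Eif1, rested on 1 to 6 counts per library.

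The 2 libraries differed from each other by more than counting noise. Across the 8932 genes the Pearson correlation of log2(TPM + 1) was -0.23 and Spearman's was -0.14. Of the genes with any count, 2626 were counted in replicate 1 only and 2966 in replicate 2 only. Because this set takes in every gene with a read in either library, such genes lower the coefficients, which do not measure a difference beyond counting noise. Among the 392 genes with at least 10 counts, the coefficients were 0.46 and 0.49. These are correlations across genes, which are not independent replicates. The chi-square of the counts over those genes was 1998 on 391 degrees of freedom, so the libraries are not copies of each other. Single genes with large differences, such as ENSMUSG00000045999 (1983 and 1027 counts) and Mir124-2hg (219 and 1), add to that sum. It therefore does not describe the 392 genes in general, and it used annotated gene counts without TMM factors. The common biological coefficient of variation from edgeR was 0.47.

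The scaled TPM of 19 genes differed at least 2-fold with deposited credibility intervals that did not overlap, 6 higher in replicate 2 and 13 higher in replicate 1. Count ratios are given relative to each library's annotated gene counts. Among the named genes counted in both libraries, the largest was that of Mir124-2hg, the host transcript of a neuronal microRNA (chromosome 3, 17789921 to 17808970, GRCm38). It had 219 counts in replicate 1 and 1 in replicate 2 (223-fold, exact binomial 95% interval 39.6 to 8849). Genes at 0 in 1 library have only a lower bound and were not ranked. Hoxb9, a homeobox gene (chromosome 11, 96271457 to 96276595), had 21 counts against 0, at least 7.13-fold higher in replicate 1 against a floor of 3 counts, a bound that leaves out the counting error of the 21. Slc6a11, an astrocytic GABA transporter, had 31 against 4 (7.89-fold, 2.79 to 30.8), and Cdhr1 had 10 against 1 (10.2-fold, 1.45 to 442). Gm13340 and Gm28439, pseudogenes with mitochondrial sequence whose reads cannot be told apart with certainty from those of the mitochondrial genes, were 8.58-fold and 9.02-fold higher in replicate 1, as was mt-Nd2 by 4.37-fold. Higher in replicate 2 were Tmsb4x (30 against 6 counts, 4.91-fold, 2.01 to 14.4), Eif3c, a translation initiation factor (11 against 1, 10.8-fold, 1.57 to 465), mt-Atp8 (4.55-fold) and Gm20594 (29.1 against 0, at least 9.52-fold against the same floor). The counts of Gm20594 in replicate 2 (29.09) and of mt-Atp8 in replicate 1 (6.48) were not whole. Part of their reads was shared with other rows, so both ratios are uncertain. The ratios of all named genes compare 2 libraries of 1 group, not conditions.

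**Figure D3:**
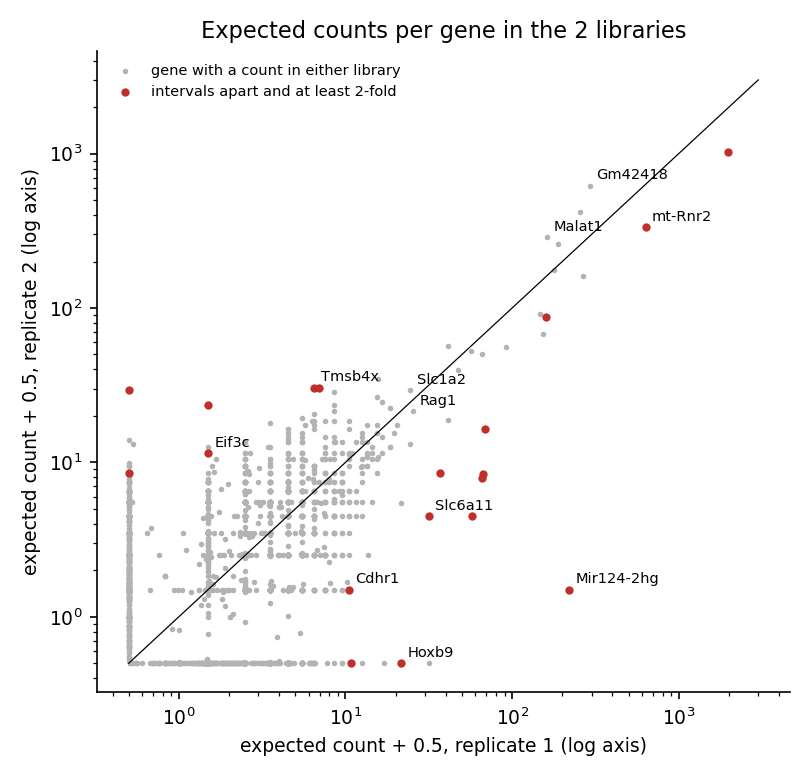
Expected counts per gene in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with 0.5 added to each count and the line of equal values. Grey points are genes with a count in either library, and the 19 red points differed at least 2-fold in scaled TPM with credibility intervals apart, among them Mir124-2hg with 219 counts against 1.

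Of the 22 lists with enough detected members, 1 had a median log2 ratio outside the central 95% of random lists matched on expression, where chance gives 1.1. It was the olfactory sensory neuron list, with a median of 5.34 (97.9th percentile) over 4 genes that had 1 count each: Gng13, Stoml3 and Adcy3 in replicate 2 and Gnal in replicate 1. By summed counts, tested after seeing the data, the interval of the cell division list excluded equality among 24 lists (2.85-fold higher in replicate 2, exact binomial 95% interval 1.35 to 6.55). Counting noise gives at most 1.2 such lists, and fewer where lists hold few counts, because exact intervals are then wider than their level. The interval of the cell division list covers counting error only, and the libraries varied by more than that.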

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

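Rows outside the comparisons held counts above the 3 that a count of 0 allows. The phiX174 row had 22472 expected counts in replicate 1 and 17985 in replicate 2, which is 56.6% and 50.7% of all counts in the gene tables. The 26248 tRNA rows summed to 45.99 and 20.99 counts, or 0.116% and 0.0591%, with 40 and 29 rows counted. The mitochondrial tRNA genes, which stayed among the annotated genes, had 11 and 3 counts. No explanation of these values was tested. The group holds 2 samples, too few to single one out.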

How the results depend on the processing

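The alternatives that count reads in place of a TPM minimum, and the summed list counts, were chosen after seeing the data. Over all alternatives 37 values stayed within 1.5 times of the reported one or within 1 SD between replicates, 10 moved and 1 reversed. With 2 libraries, leaving 1 out always stays within 1 SD of their mean. This rule judged the GABAergic sum, the ratio of Gad1 and Gad2 to the glutamate transporters and the main isoform share. Their leave-one-out values could therefore not move. A minimum of 0.1 TPM took in 8943 genes against 8932, so it could hardly change a result. The number of lists outside its range stayed at 1, but by summed counts it was cell division among 24 lists in place of olfactory sensory neurons among 22. With the posterior mean TPM, which gives rows without reads a value above 0 by its construction, 33555 genes and 1265 chemoreceptor genes passed 1 TPM, the GABAergic genes summed to 115.43 TPM in place of 1486, and the median main isoform share was 43.6%. Requiring 1 TPM in both libraries left 3346 genes in place of 8932. Requiring at least 10 counts in total left 392 genes and gave a median main isoform share of 66.4%. With that minimum the Pearson correlation between the libraries turned from -0.23 to 0.458. Genes counted in 1 library only lower the coefficient over the 8932 genes. Whether they account for all of that turn was not tested. Of 140 list members detected, 61 had at least 3 counts in total. Rescaling over nuclear protein-coding genes raised the GABAergic sum to 3737 TPM, because phiX174 and other rows no longer took a share. The coefficient of variation was 0.0001 as the median of DESeq2's gene-wise estimates, which is that tool's lower limit, against 0.47 in edgeR. Leaving out each replicate in turn gave 5971 to 6312 genes, 99 to 102 list members, 934 TPM (without replicate 2) to 2037 TPM (without replicate 1) for the GABAergic genes and 8.04 to 13.9 for the ratio of Gad1 and Gad2 to the glutamate transporters. It left the main isoform share at 100% and chemoreceptors at 0. The number of genes that differed between the libraries stayed between 18 and 23 over its alternatives. No paired analysis was possible because there is 1 group. Depth limits the results: 92 and 130 genes had at least 10 counts in the 2 libraries.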

Other observations

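In this part, the tests of mature T cells, of a tissue without neurons and of counting noise were chosen after the results were seen. The test of the second T-lineage panel and that of amplified fragments were written before their values were looked at, on patterns already noticed.

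Panels of other organs, put together after the T-lineage genes were seen, were low. Over both libraries the second T-lineage panel had 3.03 counts per gene, against 1.4 for heart, 0.5 for B cells, 0.3 for lung, 0.2 for intestine, 0.1 for neutrophils and monocytes, and 0 for liver, testis, skeletal muscle, kidney and 4 hemoglobin genes. The heart value came mostly from Ryr2 (4 and 9 counts), a calcium channel that neurons also express. The second T-lineage panel also holds genes known in brain cells, such as Ets1 (6 and 8 counts). Its 3.03 counts per gene were not reduced for them. The tubulin genes, 11 of 17 counted, had 43.6 and 26.8 counts.

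The T-lineage genes were counted at similar levels in both libraries, 180 and 185 counts over 51 genes, and the most abundant by TPM, Cd3g (390 ± 152), Cd4 (381 ± 320) and Arpp21 (363 ± 194; SD, n = 2), were in the panel put together after values were seen. Mature T cells in the tissue would not carry Rag1, Rag2 and Dntt, genes of antigen receptor assembly in immature lymphocytes. These summed to 64 counts over both libraries, 18 of them without Rag1 (12 in replicate 1 and 6 in replicate 2). Mature T cells alone would not give these counts, but they could still hold part of the other T-lineage counts. Because this test was chosen after the counts were seen, it adds no independent support. Libraries of a tissue without neurons under this label would lack neuronal transcripts, and the 20 neuronal genes summed to 232 counts, which does not bear on another neural tissue. A candidate explanation is reads or RNA from thymus. The 30 genes not looked at before summed to 91 counts, more per gene than each of 9 other panels. Lat was the most abundant of the 30 (212 ± 38.1 TPM). None of the 9 panels stood for another source of T cells. The test therefore bears on T-lineage RNA and cannot tell thymus from other T cells. Not every T-lineage gene was counted. Ptcra in the first panel and Cd5, Zap70, Gata3 and Tox in the second stood at 0 in both libraries, and Rag2 had 3 and 0 counts. Brain cells also express some of the T-lineage genes, such as Satb1, Arpp21 and Ptprc in the first panel and Ets1 in the second. Without such genes and without Rag1, whose transcript has also been reported in brain, 38 genes had 97 and 88 counts. Bcl11b is 1 panel gene also held by a fixed list. Reads carried over between libraries and mixing of tissue or RNA stay open, and no other biological explanation was tested.

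The unequal counts of single genes in the 2 libraries were more frequent than counting noise alone gives. Of 392 genes with at least 10 counts, 38 (9.69%) lay outside the central 99% binomial interval, against 3.92 expected. A few amplified fragments, such as one behind the 219 counts of Mir124-2hg, would leave the median gene near its chance value. The median squared difference was 2.35 times that value (bootstrap 95% interval 1.68 to 2.77), and the bound of 2 set for this test lies within the interval, so the test leaves it open. Differences between animals or dissections stay open and were not tested.

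The deposited listings give the size of signal tracks that were not analysed here. The track of unique reads has 16277054 bytes for replicate 1 and 18386919 for replicate 2, or 948 and 1052 bytes per count in annotated genes. A file size is no read count, so the depth of those tracks is unknown. Whether the tables count all reads of the libraries was not tested. If they do not, the low counts, the floors and the genes at 0 are properties of the tables and not of the libraries.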
